A study of Mus musculus with 84 samples.

How the data were processed

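Small RNA libraries were made from 84 tissue samples of C57BL/6 mice, taken from individual fetuses per the labels. Dams received poly(I:C), a synthetic double-stranded RNA that mimics viral infection, at 20 mg/kg by intraperitoneal injection, or saline, at E11.5 and E12.5, per the labels' protocols. Placenta with decidua was taken at 3, 6, 12, 24, 48 and 144 h after the second injection, and fetal brain and fetal liver at 24 h from saline dams. RNA was extracted with Trizol, and libraries were made from 0.2 to 1 µg RNA with a NEBNext small RNA kit and gel selection of inserts of 15 to 50 nt, per the labels' protocols. The submitters' processing notes name cutadapt 1.15, STAR 2.5.4 and the mm10 build without giving their roles, and the name of the table names the annotation tool unitas without a version.

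The authors deposited 1 table of expected counts for all 84 libraries with 3069 features, of which 2605 are mature miRNAs and 464 are tRNA fragments (58 anticodons in 8 fragment classes). Of its values, 12.8% are not whole numbers, so the deposited expected counts hold reads divided between features. The Gly GCC tiR5 value is a whole multiple of one thirtieth, within a tolerance of 0.02, in all placenta/decidua libraries of 12, 24 and 48 h and in 3 of the other libraries. How the division was done is not stated. The table keeps old and new names of some miRNAs side by side (miR-21 and miR-21a, miR-142 and miR-142a, miR-451 and miR-451a, miR-9 and miR-9-1, miR-124 and miR-124-1, miR-292 and miR-292a). Reads of such pairs could be split between them, so their single levels are uncertain. A tRNA fragment feature adds up all tRNA genes of 1 anticodon, so it has no single position. Fragment classes are named as in the table: tiR5 and tiR3 are the long 5' and 3' fragments of a tRNA broken at its anticodon loop, tRF5 and tRF3 shorter fragments of the ends, tRF3CCA 3' fragments with the added CCA, tRF1 the trailer of the precursor, leader its 5' leader, and misc internal or other fragments. miRNA positions came from the mm10 annotation.

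Counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Libraries were scaled by TMM over all features, features were kept by filterByExpr (min.count 10, min.total.count 15), and robust quasi-likelihood F tests with Benjamini-Hochberg adjustment were called at an adjusted p of 0.05. edgeR's prior count was 0.125. Standard errors are the unshrunk log2 fold change divided by the square root of F. Levels are CPM, counts scaled to a common library total, after TMM, except where given as CPM of the library total alone. Each time was fitted alone with sex as a term. Further tests were treatment by sex at each time, treatment by time over all 72 placenta/decidua libraries, male against female in each tissue under saline (placenta/decidua with time as a factor), the 3 tissues against each other at 24 h under saline, and the times of saline placenta/decidua against each other. The share of counts in tRNA fragments and in each fragment class was compared with exact two-sided permutation tests of the difference of means (Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6). Figures were drawn with matplotlib 3.10.9.

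Lists of related small RNAs covered cell type markers (erythroid, leukocyte, hepatocyte, neural, smooth muscle, striated muscle, endothelial, epithelial), inflammation-responsive, hypoxia and p53-responsive miRNAs, the miR-29 and let-7 families, the miR-17-92 and miR-106b-25, miR-290-295, Dlk1-Dio3, Sfmbt2 and X-linked miR-322-503 clusters, all X-linked miRNAs, and the 5', 3', tRF-1, other and mitochondrial tRNA fragments, with a list of the 5' fragments of 7 abundant tRNAs (Gly-GCC, Glu-CTC, Lys-CTT, Val-CAC, Val-AAC, His-GTG and Asp-GTC). The lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons of a family. Camera with an estimated correlation and fry were run beside it. The list of mitochondrial tRNA fragments has 0 members in the table and was not tested.

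Genes were named by a rule. Among features past the threshold with a mean of at least 50 CPM, it takes the 8 with the largest change in each direction, the 6 most abundant, and every passing member of a list. Where fewer than 5 features passed, it takes the 5 with the smallest p, at any abundance. miR-155-5p, miR-146a-5p and miR-21a-5p were taken at every time, and miR-122, miR-451a, miR-9 and miR-124 in every tissue. Design, lists, naming rule and the first set of alternative settings were fixed before the data were examined.

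The alternative settings of that set were DESeq2 size factors, library totals without TMM, separate scaling of miRNAs and tRNA fragments, no filter, DESeq2 1.42.0 as the test, all 72 placenta/decidua libraries in one fit, counts summed over the male and the female of a number, limma-voom with the number as a random block, the replicate number as a block, each library left out in turn, and shares without the most abundant feature of each class. Added after the data were seen were the 5' tiR share as a covariate, the 3, 6 and 144 h and the 12, 24 and 48 h libraries fitted apart, the 3 and 144 h libraries fitted alone, placenta/decidua of 3 h as the reference of the fetal tissues, and thinning of deeper libraries. The labels do not say what a replicate number means. Same-numbered libraries were taken as paired where, with 3 or more pairs, every pair's deviations from the group means correlated above 0.1, which held for male with female in fetal brain (r of 0.883 to 0.943) and fetal liver (r of 0.930 to 0.967), so blocked values stand beside those comparisons. Brain and liver of the same number were also paired by this rule (r of 0.553 to 0.759), as were male and female placenta/decidua in both arms of 24 and 48 h and in the poly(I:C) arms of 3 and 144 h. Control and poly(I:C) libraries were paired in the females of 24 h and the males of 48 h but not in both sexes of a time with 3 or more pairs. At 12 h, with 2 pairs in each sex (r of 0.511 in males and 0.499 in females), deviations from the mean of 2 libraries mirror each other, so the rule was not applied.

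The edgeR and DESeq2 fits and the list tests were run on counts simulated from the real means and library sizes with 100 features changed 1.5-fold and 100 changed 3-fold. At 3 h, 66% of the former and 98% of the latter were recovered among 1306 tested. At 48 h 24% and 91% were recovered among 1114, in male against female placenta/decidua 85% and 100% among 1307, in fetal brain 3% and 60% among 1476, and in fetal liver 0% and 25% among 1267. Unchanged features made up 16% of the simulated calls in fetal brain (12 of 75) and 7.41% in fetal liver. They made up 7.89% and 5.71% in treatment by sex at 12 and 144 h, 5.81% in poly(I:C) against saline at 12 h and 4.9% or less elsewhere. Camera called 0 of 20 unchanged lists and found the changed list in each simulated comparison. The features were simulated independently of each other, so this does not show how often camera calls unchanged lists of correlated features. The permutation test of shares, run on 1000 sets of simulated shares, passed in 4.7% without a difference and in 100% with a shift of 3 SD. The other steps had no simulated test. No sample and no column of the table was left out.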

Results

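The small RNA pool of the mouse placenta with decidua was measured after maternal poly(I:C) injection, an immune activation that mimics viral infection during pregnancy. Placenta/decidua gave 36 saline and 36 poly(I:C) libraries. At 3, 6, 24 and 48 h each treatment had 3 male and 3 female libraries, at 12 h it had 2 of each sex and at 144 h 4 of each. Fetal brain and fetal liver gave 6 saline libraries each at 24 h (E13.5), 3 male and 3 female. The total count per library ran from 3069087 to 123700277, with a median of 6673492. In units of 1e6 counts, the medians of the arms lay between 3.72 (48 h, poly(I:C)) and 9.20 (3 h, saline) in placenta/decidua, at 5.82 in liver and at 14.2 in brain. The labels of the tissues were checked with miRNAs of known tissue. miR-122-5p, the abundant miRNA of hepatocytes, stood at 44119 CPM of the library total in liver, 23.9 in brain and 41.9 in placenta/decidua of 24 h. miR-9-5p, a neural miRNA, stood at 86639 CPM in brain against 63.4 in liver and 13 in placenta/decidua, and miR-124-3p at 250 against 0.227 and 1.23 CPM. miR-451a, a red cell miRNA, stood at 434 CPM in liver, 4.75 in brain and 31.3 in placenta/decidua.

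The first question was what differs in the placenta/decidua within hours of the second poly(I:C) injection. The same dams had also been injected at E11.5, and no group had a single injection. Effects of the first and of the second dose therefore cannot be told apart at any time. At 3 h after the second injection, part of the 3' tRNA fragments that end in CCA rose and part of the long 5' fragments (tiR5) fell. Of 40 tRF3CCA fragments tested, 16 rose and 0 fell, and 35 had a positive change. Fragments of 1 amino acid may share divided reads, so the 16 may not be separate changes. Ala AGC, Ala TGC and Ala CGC tRF3CCA, for example, stood at 312, 311 and 290 CPM under poly(I:C) and each rose by 0.46. Gln CTG tRF3CCA rose by 0.66 ± 0.099 (log2, SE) from 241 ± 26.5 to 381 ± 52.3 CPM (SD, n = 6 each, edgeR adjusted p 0.00113), Tyr GTA tRF3CCA by 0.60 ± 0.089 and Ala AGC tRF3CCA by 0.46 ± 0.069. Of 37 tiR5 fragments, 8 fell and 0 rose. Asp GTC tiR5 fell by 0.58 ± 0.090 to 2249 ± 298 from 3368 ± 413 CPM (n = 6 each, edgeR adjusted p 0.00119). Gly CCC tiR5, at 29813 ± 5202 CPM under saline, fell by 0.62 ± 0.13, and Glu TTC tiR5 by 0.52 ± 0.096. The trailer fragments Trp CCA tRF1, Ser AGA tRF1 and Asp GTC tRF1 fell, by 0.64, 0.79 and 0.36. Of 29 tiR3 fragments 2 fell, Gly GCC tiR3 by 0.63 and Glu CTC tiR3 by 0.39, while 2 tRF3 and 1 tRF5 fragments (Gln TTG tRF5, 0.71) rose and the misc fragments Leu CAA misc and Cys GCA misc moved apart, by 0.34 and -0.36.

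Among 1045 miRNAs tested at 3 h, 20 rose and 2 fell. The smallest p belonged to miR-291b-5p, a member of the miR-290-295 cluster of early embryonic and trophoblast cells (mm10 chromosome 7, 3219482 to 3219560), which rose by 0.52 ± 0.067 from 150 ± 3.56 to 215 ± 14.9 CPM (n = 6 each, edgeR adjusted p 0.000675). Also higher were miR-6240-5p by 0.65 ± 0.12, miR-6236-5p by 0.56 ± 0.12 and miR-3963-5p by 0.56 ± 0.12, the last from 436 ± 52.8 to 645 ± 127 CPM. let-7g-5p (chromosome 9, 106178840 to 106178927, in an intron of Wdr82) fell by 0.24 ± 0.061 to 9479 ± 776 from 11154 ± 319 CPM. The best known miRNAs of inflammation did not pass. miR-155-5p stood at 395 against 385 CPM (log2 change 0.04 ± 0.091), miR-146a-5p at 948 against 939 and miR-21a-5p at 11671 against 12691, with edgeR adjusted p of 0.858, 0.916 and 0.387 (n = 6 each). Of 17 inflammation-responsive miRNAs tested 14 had a positive change and 0 passed (camera adjusted p 0.377).

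**Figure D1:**
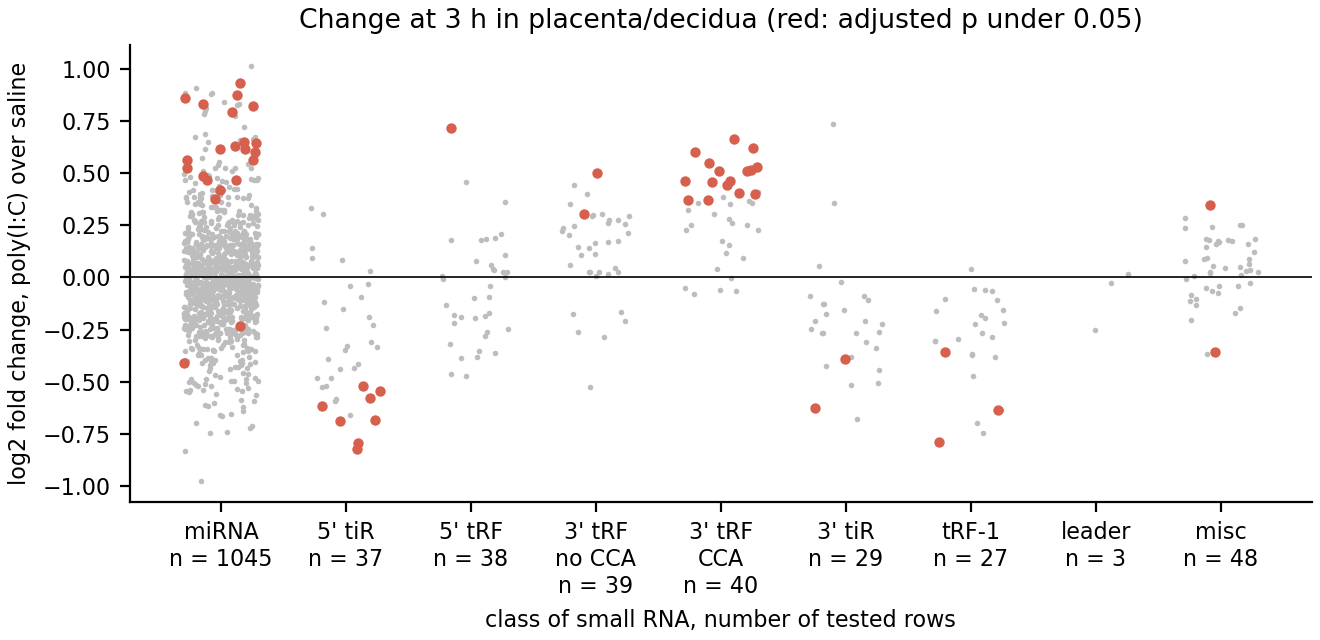
Log2 fold change of poly(I:C) against saline at 3 h (vertical axis) of each tested small RNA, grouped by class (horizontal axis), with the small RNAs past the threshold marked; the median was 0.36 for tRF3CCA and -0.39 for tiR5 fragments.

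In all, 56 of 1306 small RNAs passed at 3 h, 40 higher and 16 lower (269 had an unadjusted p under 0.05). Each of the 56 moved in one direction in both sexes, and in 36 the groups did not overlap. The calls were selected by their p, so this adds little to it; over all 1306 tested, 53 had groups that did not overlap, where chance gives 0.216%. As lists, the 5' fragments (75 tested, 1 rose and 8 fell, 1 and 10 adjusted over the list alone) and the tRF-1 fragments (27 tested, 3 fell, 8 adjusted over the list alone) lay lower, with camera adjusted p of 3.8e-06 and 3.5e-07. The 3' fragments (108 tested, 18 rose and 2 fell, 30 and 5 adjusted over the list alone) lay higher at 1.8e-05. None of these 3 lists passed with an estimated correlation (adjusted p of 0.79, 0.76 and 0.76). The tRF1 share of counts at 3 h was 0.428% under poly(I:C) and 0.423% under saline (exact permutation p 0.916). The lower tRF-1 list, found after TMM, was thus not seen in the counts of that class as a whole. The split of calls depended on the scaling: with library totals alone 118 were higher and 8 lower, and the median of all small RNAs moved by 0.145. With all 72 placenta/decidua libraries in one fit 16 passed at 3 h (14 and 2), 15 of them among the 56. With every library left out in turn, 23 of the 40 named and called small RNAs kept passing, and let-7g-5p did not pass without saline female 1, male 2, female 2, male 3, female 3 or poly(I:C) male 3 (adjusted p up to 0.091).

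The balance of the pool was compared next. tRNA fragments made up 39.2% ± 5.24 of the counts under poly(I:C) and 46.8% ± 3.64 under saline at 3 h (SD, n = 6 each). All 6 poly(I:C) libraries lay below the saline mean, but the groups overlapped (highest 44.8% under poly(I:C), lowest 43.7% under saline). The exact permutation p of 0.0152 did not pass over the 6 times (adjusted 0.0909, but 0.039 without poly(I:C) male 3 or female 3, with differences of -8.75 and -8.80 percentage points). At 6 h the shares were 39.96% and 43.8%, at 24 h 60.5% ± 3.95 and 58% ± 1.52, and at 48 h 35.4% and 35.5%. The tiR5 share at 3 h, 34.2% ± 5.28 against 42.5% ± 4.03, did not pass over 48 tests of single classes (exact permutation test, n = 6, adjusted p 0.0649). Other classes did: tRF3CCA made up 0.304% ± 0.0348 against 0.202% ± 0.0175 of counts at 3 h and fell at 24 h, at 0.136% ± 0.0101 against 0.164% ± 0.0159 (exact permutation tests, n = 6, adjusted p 0.0297 each). The tRF3 share rose at 3 h and fell at 24 h, the tRF1 share fell at 24 h, and the misc share rose at 3 h and at 48 h (0.963% against 0.887% and 1.11% against 0.893%), with the adjusted p of 0.0297 for each. These tests take the libraries as independent, though male and female of a number were paired in both arms of 24 and 48 h and in the poly(I:C) arm of 3 h. With the 3 numbers of each arm as units the smallest p they can give is 0.1, so none would pass. Shares add up to the whole, so the lower tiR5 share at 3 h by itself raises the other shares. The rise of the misc share at 3 h was not tested relative to miRNAs, so it cannot be told from that effect. At 24 h the tiR5 share was 57.9% against 55.1% (exact permutation test, adjusted p 0.423), which by itself lowers the others. The fall of the tRF1 share at 24 h was not tested relative to miRNAs either.

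**Figure D2:**
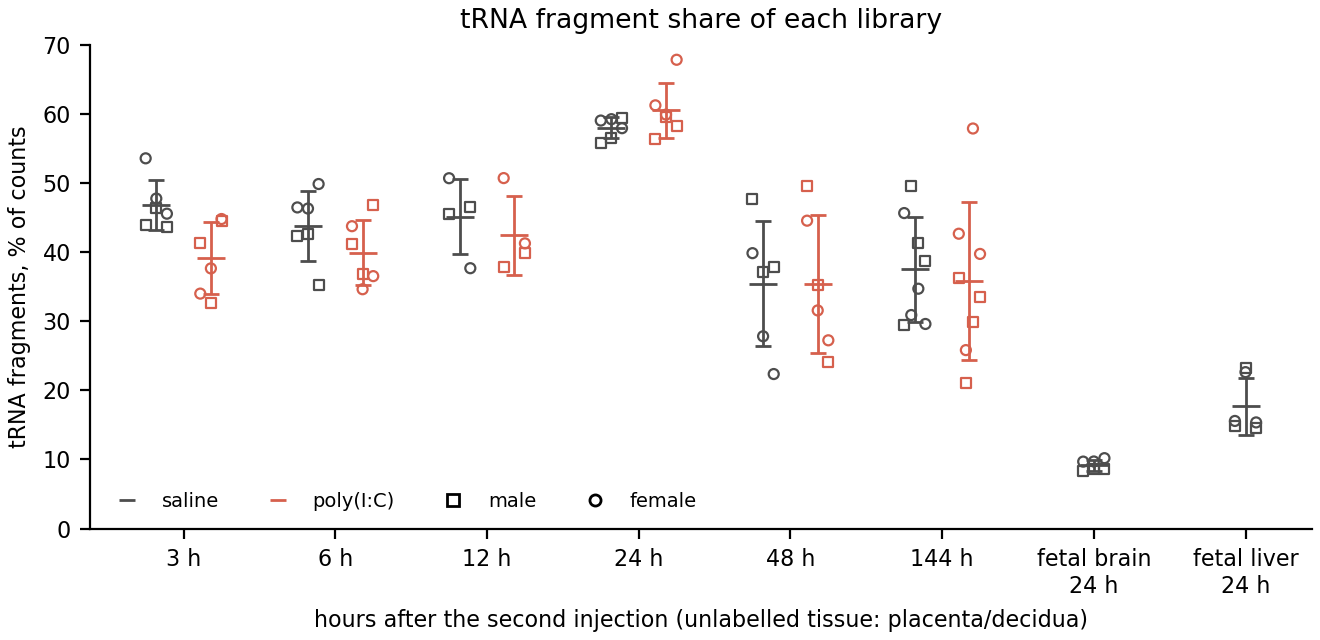
Share of counts in tRNA fragments in percent (vertical axis) for each library by tissue, time and treatment (horizontal axis), with the mean and SD of each group; saline placenta/decidua held 58% at 24 h, against 9.17% in brain and 17.7% in liver.

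At 6 h, other tRNA fragments moved and 5 of the 3 h calls were seen again. Trailer fragments fell: Ser GCT tRF1 by 0.55 ± 0.11, Asp GTC tRF1 by 0.42 ± 0.096 (112 against 149 CPM) and Ser AGA tRF1 by 0.54. Among internal fragments Gly TCC misc rose by 0.55 ± 0.10 (60.4 against 41 CPM, n = 6 each, edgeR adjusted p 0.0076), SeC TCA misc by 0.70 ± 0.13 and Asp GTC misc by 0.48 ± 0.11, while Asp GTC leader fell by 0.77 ± 0.17. miR-6240-3p rose by 1.10 ± 0.22 from 733 ± 206 to 1599 ± 564 CPM, miR-7079-3p rose by 0.69 and miR-6390-5p fell by 0.61 ± 0.13. miR-155-5p, miR-146a-5p and miR-21a-5p did not pass here or at any later time.

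At 6 h 14 of 1290 small RNAs passed, 9 higher and 5 lower (112 with an unadjusted p under 0.05), all 14 with one sign in both sexes, and in 10 the groups did not overlap (13 of all 1290 tested, chance 0.216%). With library totals alone 17 were higher and 0 lower, and the median of all small RNAs moved by 0.115, more than the -0.10 at which the Sfmbt2 list had its median. The calls shared with 3 h were Asp GTC tRF1, Ser AGA tRF1, miR-6238-3p, miR-6390-5p and miR-6538-5p, where 0.623 would be shared by independent lists, and 52 of the 56 calls of 3 h had the same sign at 6 h. Camera called the tRF-1 fragments (23 of 27 negative, 9.3e-09), the 5' fragments (52 of 74 negative, 0.0004) with those of the 7 abundant tRNAs (11 of 14 negative, 0.0073), and the Sfmbt2 cluster, a rodent miRNA cluster of trophoblast (61 of 79 negative, 0.0004), lower, and other tRNA fragments higher (39 of 51, 0.010). None passed with an estimated correlation (adjusted p of 0.66 to 0.84). The tRF1 share of counts at 6 h was 0.396% under poly(I:C) and 0.420% under saline and did not pass (exact permutation p 0.498). Counts of 6 h calls fell to 9 without saline female 1, saline male 3 or poly(I:C) male 1, to 8 without poly(I:C) female 1 and to 7 without saline male 2. Of the 10 named and called small RNAs of 6 h, 3 kept passing with every library left out and 2 under every scaling.

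At 24 h few small RNAs passed, and those that did rose. Thr TGT tiR5 rose by 0.89 ± 0.16 (43.4 against 23.6 CPM) and Trp CCA tiR3 by 0.77 ± 0.16. miR-124-1-3p, an arm of a neural miRNA (chromosome 14, 64590657 to 64590741), rose by 1.23 ± 0.23 from 6.6 ± 1.41 to 15.8 ± 6.03 CPM (n = 6 each, edgeR adjusted p 0.0202). The entry miR-124-3p, with which it may share reads, held 0.000153% ± 5.43e-05 of counts under poly(I:C) and 0.000123% ± 3.96e-05 under saline (SD). Arg ACG tRF5 (3.57 against 0.675 CPM) and Arg TCT tRF5 (13.8 against 5.20 CPM, above the saline mean in 5 of 6 libraries) rose from levels near the floor. The miR-290-295 cluster lay higher as a list: 13 of 13 members had a positive change, with a median of 0.30, and 5 passed when adjusted over the list alone while 0 passed over all tested (camera adjusted p 8.7e-05, fry 0.00338, but adjusted p 0.127 with an estimated correlation). The 5' fragments lay higher (53 of 74 positive, 3 rose, 0.00023) and the Sfmbt2 cluster lower (46 of 75 negative, 0.025), with adjusted p of 0.795 and 0.763 with an estimated correlation. In all 5 of 1131 passed, 5 higher and 0 lower (167 with an unadjusted p under 0.05). DESeq2 called 24, 12 in each direction, all 72 libraries in one fit gave 22 (19 and 3, 2 of the 5 among them), the replicate block 17 (11 and 6), no filter 12, limma-voom 3 and counts summed over a number 1, and the count was 3 without saline female 1, saline male 2 or saline female 3. miR-124-1-3p stopped passing without saline male 1, female 1, male 2, male 3, female 3 or poly(I:C) female 2 (adjusted p up to 0.084). Of the 5 calls, 3 kept passing with every library left out.

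Lists of other cells and states did not pass at 24 h. Camera adjusted p were 0.581 for leukocyte, 0.834 for erythroid, 0.869 for hepatocyte, 0.940 for neural, 0.877 for smooth muscle, 0.685 for striated muscle, 0.552 for endothelial and 0.586 for epithelial miRNAs. They were 0.374 for inflammation-responsive, 0.938 for hypoxia and 0.977 for p53-responsive miRNAs, 0.0906 for the miR-29 family (6 of 6 positive) and 0.316 for let-7. The miR-17-92 and miR-106b-25 clusters, the Dlk1-Dio3 cluster and the miR-322-503 cluster gave 0.337, 0.369 and 0.337.

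At 48 h miR-3089-3p (chromosome 2, 30721210 to 30721293) rose by 1.03 ± 0.16 from 15.4 ± 1.88 to 31.2 ± 6.38 CPM (n = 6 each, edgeR adjusted p 0.0145), the 1 small RNA of 1114 that passed (83 with an unadjusted p under 0.05). It did not pass with library totals alone, with male and female counts of a number summed or with limma-voom (0 calls each), while all 72 libraries in one fit gave 28 (26 higher, 2 lower) and no filter gave 9. The count was 2 without poly(I:C) male 1 or female 1, and miR-3089-3p stopped passing, leaving 0, without saline male 2, saline male 3 or poly(I:C) female 3 (adjusted p up to 0.075). Next by p were Glu TTC misc at 477 against 323 CPM (adjusted p 0.186) and miR-144-5p, a red cell miRNA, at 58.5 against 92.8 CPM (adjusted p 0.368, edgeR), which did not pass. As lists, the other tRNA fragments lay higher (48 of 51 positive, median 0.22, camera adjusted p 5.4e-09) and the erythroid miRNAs (7 of 7 negative, 0.0041) and the Sfmbt2 cluster (62 of 74 negative, 7e-06) lower, none with an estimated correlation (adjusted p of 0.13, 0.76 and 0.76).

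At 12 h edgeR called 0 of 1155 small RNAs (30 with an unadjusted p under 0.05), or 1 without saline female 2, and DESeq2 called 0. miR-291b-5p stood among the 5 smallest p with a change of 0.40 ± 0.12, without passing, as did miR-6937-5p with 0.64 ± 0.16. By list, camera called the miR-290-295 cluster (12 of 13 positive, 0.019) and the tRF-1 fragments (23 of 27 positive, 0.0005) higher, and the 5' (53 of 70 negative, 6.9e-06) and 3' fragments (73 of 107 negative, 0.011) lower, all lost with an estimated correlation (adjusted p 0.77, 0.76, 0.88 and 0.79). At 144 h (E18.5) edgeR called 0 of 1163 (50 with an unadjusted p under 0.05) and DESeq2 1. The count was 1 without poly(I:C) male 1 or saline male 4 and 2 without poly(I:C) female 3. Thr CGT tRF1 had the smallest p, with a change of 0.40 ± 0.078 (n = 8 each, edgeR adjusted p 0.0673). The tRF-1 list lay higher, with 21 of 21 positive, 4 past the threshold adjusted over the list alone and a camera adjusted p of 5.4e-09 (0.66 with an estimated correlation). let-7 (22 of 25 positive, 0.0099) lay higher, and the 5' fragments (54 of 70 negative, 0.00016) and those of the 7 abundant tRNAs (13 of 14 negative, 0.011) lower. These 3 did not pass with an estimated correlation (adjusted p of 0.79, 0.88 and 0.88).

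Whether the response differed between times was tested over all 72 libraries. It differed for 25 of 1420 small RNAs, 16 of them tRNA fragments and 9 miRNAs. The trailer Asp GTC tRF1 went from -0.36 and -0.42 at 3 and 6 h to 0.26 at 144 h, and Thr CGT tRF1 from -0.16 and -0.31 to 0.40. The 3' fragment Ala TGC tRF3CCA went from 0.46 at 3 h to -0.32 at 24 h. The internal fragments SeC TCA misc and Asp GTC misc stood highest at 6 h (0.70) and at 48 h (0.75). miR-124-1-3p had its largest change at 24 h with 1.23, as did miR-29b-3p with 3.94, which did not pass at that time alone. The adjusted p (edgeR) were 0.00203 for SeC TCA misc, 0.00337 for Asp GTC tRF1 and Thr CGT tRF1, 0.00561 for Asp GTC misc, 0.0104 for Ala TGC tRF3CCA and 0.0339 for both miRNAs. The count was 2 with library totals alone, 14 with separate scaling of miRNAs and tRNA fragments and 10 without the filter. It was 14 to 16 without 3 h saline male 1, female 1 or male 2, 3 h poly(I:C) male 3 or 24 h saline male 2, and those 14 to 16 were all among the 25.

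**Figure D3:**
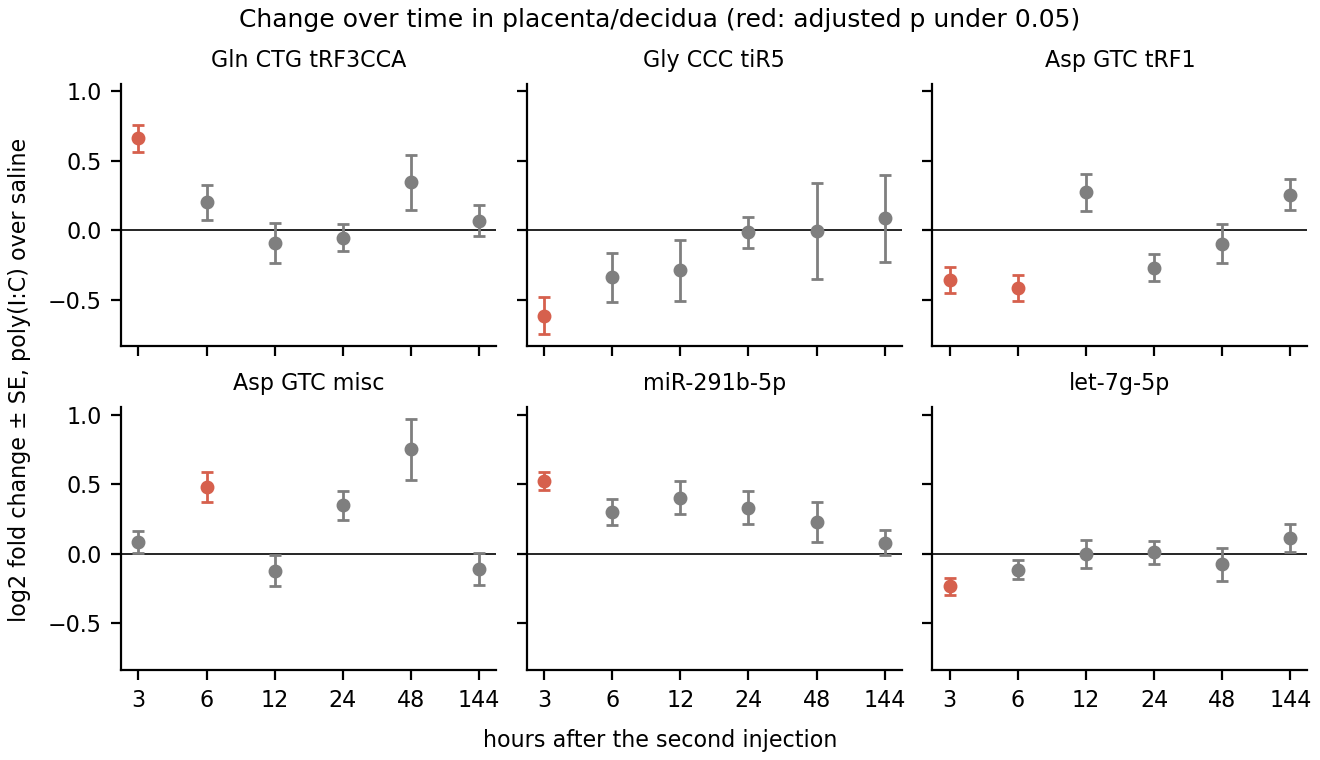
Log2 fold change of poly(I:C) against saline with its SE (vertical axis) at each time after the second injection (horizontal axis) for small RNAs whose response differed between times; Asp GTC tRF1 lay below 0 at 3 and 6 h and above it at 144 h.

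A difference of the response between the sexes was called for 1 small RNA at 1 time. At 12 h miR-28c-3p (chromosome 15, 53614205 to 53614279, in an intron of Samd12) stood at 8.63 CPM in saline males and 2.35 in poly(I:C) males, but at 0.912 and 4.39 in females, a difference of -4.07 ± 0.61 (log2, n = 2 each, edgeR adjusted p 0.0123). It did not pass with the replicate number as a block or without saline male 1 (adjusted p 0.062), and the count was 2 without poly(I:C) male 1 or female 2 and 3 without poly(I:C) female 1. At 3, 6, 24, 48 and 144 h edgeR called 0 of 1350, 1329, 1166, 1141 and 1216 small RNAs (54, 39, 23, 43 and 62 with an unadjusted p under 0.05), and DESeq2 called 0 at each. Leaving out 1 library gave 2 at 3 h without poly(I:C) male 2, 1 without poly(I:C) female 3, and 5 at 48 h without poly(I:C) male 1.

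Male and female were compared without treatment. In saline placenta/decidua, X-linked miRNAs lay lower in the male. miR-743a-3p (X, 66776757 to 66776818) fell by 0.43 ± 0.089, to 18.46 ± 3.99 from 24.9 ± 5.07 CPM, and miR-503-5p (X, 53053984 to 53054054), of a cluster with a role in growth control, by 0.19 ± 0.041 to 3125 ± 537 from 3586 ± 702 CPM (n = 18 each, edgeR adjusted p 0.0234 each). Of 76 X-linked miRNAs 63 were lower, with 22 lower and 1 higher past the threshold adjusted over the list alone (camera adjusted p 1.5e-15, 0.0078 with an estimated correlation and 0.055 with that and the number as a block). In the miR-322-503 cluster, whose 15 members belong to that list, 15 of 15 were lower (9.9e-08, 0.27 with an estimated correlation). Hepatocyte miRNAs lay lower (7 of 8, 0.037), and other (37 of 52, 0.0013) and 3' tRNA fragments (70 of 112, 0.015) higher, and these were lost with an estimated correlation (adjusted p of 0.46, 0.46 and 0.91). With separate scaling the 3' list turned lower (adjusted p 0.937). In all 2 of 1307 passed (96 with an unadjusted p under 0.05). The count was 0 without 6 h male 3 or 12 h male 1, 4 without 24 h female 1 and 9 without 3 h male 2, and with library totals alone it was 0.

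In fetal brain miR-10a, a miRNA of the Hox clusters that is known from the spinal cord and trunk, was higher in the 3 male libraries. miR-10a-5p (chromosome 11, 96317165 to 96317274) stood at 820 ± 73.1 against 108 ± 13.8 CPM (log2 change 2.92 ± 0.20, n = 3 each, edgeR adjusted p 0.00185) and miR-10a-3p at 10.1 against 1.46 CPM. Next by p and not passing were the Hox cluster miRNAs miR-615-3p at 130 against 22.8 CPM and miR-10b-5p at 478 against 150, and miR-205-5p at 30.1 against 154 (adjusted p 0.10 and 0.138 for the former pair). In fetal liver miR-196a-2-5p, from an intron of Hoxc5 (chromosome 15, 102973350 to 102973434), was higher in the male at 64.4 ± 19.8 against 6.15 ± 1.44 CPM (log2 change 3.39 ± 0.38, n = 3 each, edgeR adjusted p 0.0412). Not passing were the neural miR-9-1-5p at 155 against 38.3 CPM (adjusted p 0.0591) and miR-9-5p at 102 against 26.1. These were 2 of 1476 small RNAs in brain and 1 of 1267 in liver. Without 1 library the count was 1 in brain (male 1, female 1 or female 2) and 0 in liver (male 1, male 2, female 1, female 2 or female 3), or 3 without liver male 3.

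With the replicate number as a block, which paired male and female libraries in both fetal tissues, 67 small RNAs differed in brain (35 higher and 32 lower in the male) and 62 in liver (36 and 26). In brain, miR-10a-5p (2.93 ± 0.091), miR-615-3p (2.54) and miR-10b-5p (1.73) rose, as did the epithelial miR-200b-3p (1.28, 383 against 170 CPM) and miR-200a-3p (1.22), while miR-205-5p (-2.27) and miR-203-3p (-0.577), which are epithelial too, Gln CTG tRF3CCA (-0.51) and Val CAC misc (-0.49) fell. In liver, miR-196a-2-5p (3.36) and miR-9-1-5p (2.02) rose, with the striated muscle miR-206-3p (1.54, 293 against 106 CPM) and miR-1a-3p (1.18, 234 against 108 CPM) and the red cell miR-144-3p (1.14, 1250 against 556 CPM), while Trp CCA tRF3CCA (-0.53) fell. Without the block, camera called epithelial miRNAs (8 of 11 positive, 8.9e-06) and let-7 (25 of 28 positive, 0.015) higher in male brain. In male liver it called neural (17 of 22 positive, 4.4e-09), striated muscle (8 of 9, 2.6e-09) and epithelial miRNAs (9 of 10, 0.0052) higher and 3' tRNA fragments lower (97 of 126 negative, 1.7e-05). None passed with an estimated correlation (adjusted p of 0.27 to 0.46).

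**Figure D4:**
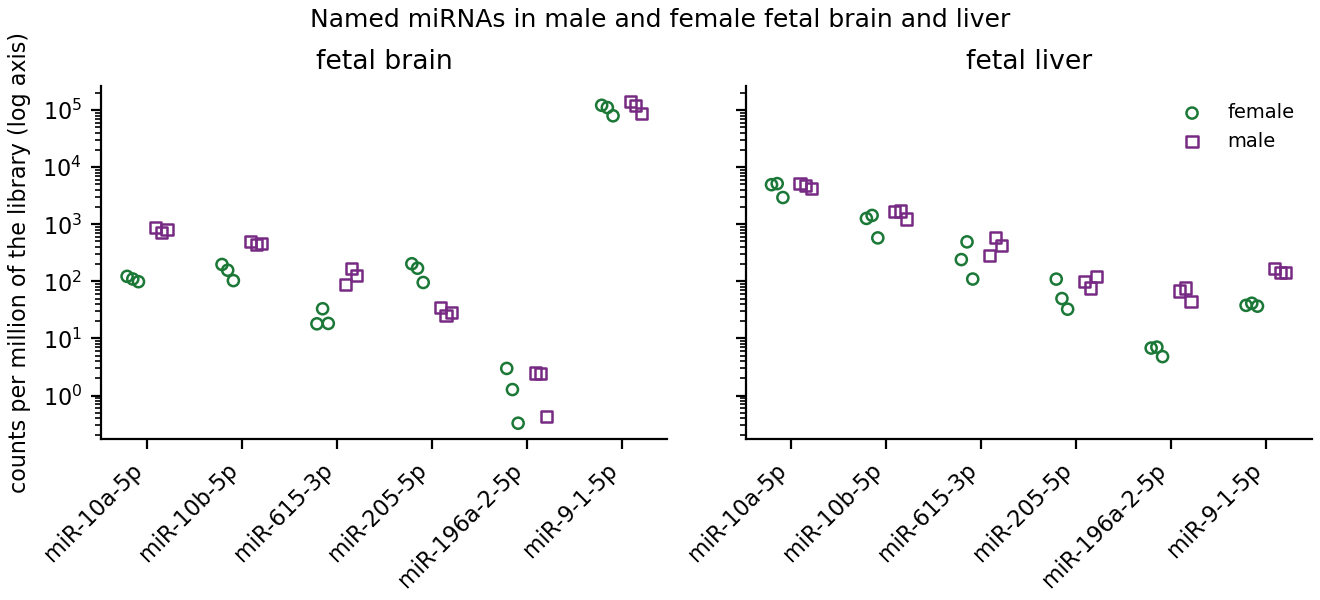
Level in CPM (vertical axis, log scale) of miRNAs that differed between the sexes in fetal brain or fetal liver, 1 point per library, by sex (horizontal axis); miR-10a-5p stood near 820 CPM in the 3 male brains and near 108 in the 3 female brains.

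The tissues were compared at 24 h under saline. Brain was set apart by its neural miRNAs: 45 of 45 tested were higher than in placenta/decidua, with a median of 5.81 (camera adjusted p 4.8e-19). miR-9-1-5p stood at 102697 ± 24061 against 41.8 CPM (log2 change 11.3 ± 0.44, n = 6 each), miR-92b-3p at 6126 against 140 and miR-124-1-3p at 626 against 11.9. The miR-17-92 and miR-106b-25 clusters, known for proliferation, were higher in brain (20 of 21, 0.00011, 0.19 with an estimated correlation). Clusters known from trophoblast marked placenta/decidua: 13 of 13 miR-290-295, 70 of 70 Sfmbt2 and 15 of 15 miR-322-503 miRNAs were lower in brain, such as miR-294-3p at 0.638 against 426 CPM and miR-503-5p at 162 against 5482 (adjusted p with an estimated correlation 0.014, 0.084 and 0.028). Also lower in brain were miR-196b-5p at 0.862 against 3856 CPM, the epithelial miR-200c-3p at 94.7 against 4655 and miR-155-5p at 35.2 against 346. The long 5' fragments set placenta/decidua apart most in amount. After TMM, Gly GCC tiR5 stood at 421889 CPM against 12914 in brain (-5.03 ± 0.24), and Glu CTC tiR5 at 268046 against 7601. These scaled values are not shares of the pool. Of the library totals, without TMM, Gly GCC tiR5 made up 24.0% against 1.40% and Glu CTC tiR5 15.3% against 0.812%, a smaller difference.

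Liver held hepatocyte and red cell miRNAs. miR-122-5p stood at 27437 ± 10343 CPM against 73.3 in placenta/decidua (8.55 ± 0.33, n = 6 each), miR-451-5p at 16296 against 1200 and miR-144-5p at 2220 against 100. Of the erythroid list 6 of 7 were higher (camera adjusted p 0.0082, 0.060 with an estimated correlation), and of the hepatocyte list 7 of 9 (0.015 and 0.11). Lower in liver were 24 of 27 let-7 miRNAs (let-7i-5p 10160 against 40114 CPM), 13 of 13 miR-290-295, 69 of 70 Sfmbt2 and 15 of 15 miR-322-503 miRNAs, and 12 of 16 inflammation-responsive miRNAs (adjusted p with an estimated correlation 0.031, 0.0016, 0.031, 0.038 and 0.038). Tyr GTA tRF3CCA stood at 1641 against 144 CPM. Between brain and liver, miR-122-5p stood at 22.3 against 27437 CPM and miR-99a-5p at 61002 against 5111. Gly GCC tiR5 was higher in brain than in liver by 0.54 (adjusted p 0.0238), which turned to -0.03 with library totals alone and did not pass without liver male 1 or female 1.

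Brain differed from placenta/decidua in 1084 of 1441 small RNAs (574 higher, 510 lower), liver in 1008 (516 and 492), and brain from liver in 978 (492 and 486). With library totals alone, which moved the medians by 0.915, 1.5 and -0.587, the splits were 827 and 369, 950 and 250, and 351 and 712. The shift of 1.5 comes close to the medians of the let-7 (-1.69) and inflammation-responsive lists (-1.54) in liver. tRNA fragments made up 9.17% ± 0.784 of counts in brain, 17.7% ± 4.10 in liver and 58% ± 1.52 in placenta/decidua (SD, n = 6 each, exact permutation p 0.00216 for each pair, the smallest that these numbers can give). These tests take the libraries as independent, though male and female of a number were paired in each tissue. With the 3 numbers of each tissue as units none could pass. The tiR5 share was 3.81%, 5.63% and 55.1%, while the tRF3CCA share ran the other way, 1.149%, 2.45% and 0.164%. Gly GCC tiR5 values in thirtieths were found in all 6 of these placenta/decidua libraries but in 0 of brain and 0 of liver. An annotation step could thus have a part in the contrast. At 3 h, with 1 such library of 6, saline placenta/decidua held 46.8%, still above both fetal tissues. With 3 h as the reference, 41 values of named small RNAs were unchanged and 1 no longer passed.

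Saline placenta/decidua differed between the times, which are also gestational ages and separate sets of libraries. From 3 h (E12.5) to 144 h (E18.5), miR-215-5p (chromosome 1, 185313581 to 185313692) rose from 307 to 3348 CPM (3.45 ± 0.10, n = 6 and 8) and the epithelial miR-141-3p from 29.8 to 372 CPM. The smooth muscle miR-143-3p rose from 9746 to 29474 CPM, with 3 of 3 smooth muscle, 10 of 12 epithelial and 12 of 14 miR-290-295 miRNAs rising (adjusted p with an estimated correlation 0.016, 0.013 and 0.016). Trailer fragments fell without exception among those tested, 27 of 27 with a median of -1.48 (0.0012 with an estimated correlation), such as Asp GTC tRF1 from 140 to 25.6 CPM. The immune miR-155-5p fell from 343 to 89.5 CPM and miR-146b-5p from 1469 to 413. Camera also called striated muscle (3 of 5 rose), p53-responsive (4 of 5 rose) and Dlk1-Dio3 miRNAs (44 rose and 11 fell of 91) higher, and the Sfmbt2 cluster (9 rose and 39 fell of 77) and other tRNA fragments (2 rose and 25 fell of 52) lower, with adjusted p of 0.16, 0.16, 0.39, 0.41 and 0.41 with an estimated correlation. In all 737 of 1307 differed (353 higher, 384 lower; 255 and 541 with library totals alone, a median shift of -0.209), and 991 differed between any of the times. The tRNA fragment share was 37.5% ± 7.63 at 144 h and 46.8% ± 3.64 at 3 h (n = 8 and 6, exact permutation p 0.0220, adjusted 0.0283).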

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

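The tests of the 3' CCA to tiR5 ratio and of the change that the tiR5 trend predicts, those with the 5' tiR share as a covariate and with thinned libraries, the tests of the share of brain RNA and of X-linked calls in the fetal tissues, the 24 h against 48 h test of the share, the tests on means by number and the search for miR-122-5p, miR-451a, miR-9-5p and miR-124-3p in all groups were chosen after the results were seen.

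At 3 h after poly(I:C), 56 small RNAs were called in placenta/decidua (16 with all 72 libraries in one fit, 15 of them shared), among them 16 of 40 tested 3' CCA fragments, which rose, and 8 of 37 long 5' fragments (tiR5), which fell; the tiR5 share did not pass (adjusted p 0.0649), nor did the lists with an estimated correlation. Scaling cannot give these unequal changes, since the log2 ratio of 3' CCA to tiR5 counts within a library, which no factor alters, differed by 0.911 (n = 6 each, exact permutation p 0.00216, the smallest that these numbers can give; 0.911 ± 0.195 (SE) on the means of the 3 numbers of each arm). With the tiR5 share of each library as a covariate 34 of the 56 stayed, which argues against that share as the whole cause, and depth (7.01 ± 1.91 and 9.15 ± 2.01 in units of 1e6 counts, n = 6 each, exact permutation p 0.0952) is argued against by 42 of the 56 calls that stayed after thinning to the smallest total (52 called). The trend with the tiR5 share among 30 saline libraries of other times is argued against for the 3' CCA rise, for which it predicts a median change of -0.0337 ± 0.0604 (jackknife SE, at most 0.0358 with 1 time left out) against 0.355 observed over the 40, but it stays open for the rest: the change and the slope had a Spearman rho over genes, which are not independent replicates, of 0.465 over the 56 (0.188 to 0.653 with 1 time left out), 0.351 over all 1306, 0.254 over 22 miRNAs and -0.274 over the 16 3' CCA fragments called. It predicts -0.436 for the 37 tiR5 (-0.389 observed), which make up that share themselves, so a response of the tissue to poly(I:C), the difference that the design names, may account for the 3' CCA rise and remains a hypothesis.

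In fetal brain and fetal liver, male and female libraries of one number were alike and differed in 67 and 62 small RNAs with the number as a block, among them the Hox cluster miRNAs miR-10a-5p, miR-615-3p and miR-196a-2-5p. Brain tissue in the male livers is argued against for 16 of the 29 liver miRNAs higher in the male, which were less abundant in brain than in liver, and for 8, which need at least 1.56% of brain RNA (rise less 2 SE) where miR-9-1-5p allows at most 0.118% in any pair, but it stays open for 4 arms of miR-9 and miR-1298-5p, which need 0.0849% to 0.357%, while 22 miRNAs as enriched in brain and not called need a median of 0.0437% (0 to 0.0845% by pair). Dosage of the X as the direct cause is argued against, since of the 85 miRNAs called in the 2 tissues 9 are X-linked, 2 of them lower in the male (5 had no position). The labels describe tissue of individual fetuses, and the values cannot tell apart whether the 3 libraries of a sex and tissue are instead repeats of 1 RNA sample: with the block the coefficient of variation was 0.11 in brain and 0.0986 in liver, within the 0.0927 to 0.207 of the placenta/decidua arms, a range that was set beforehand to count against repeats but cannot, as no known technical repeat in the series shows how far repeats vary. A sex difference of the fetal tissues and a difference in what was dissected could both give such changes and were not separated.

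The share of tRNA fragments in saline placenta/decidua differed between times, from 58% ± 1.52 at 24 h to 35.5% ± 9.03 at 48 h. The Gly GCC tiR5 values of the 12, 24 and 48 h libraries (and of 3 others) are in thirtieths, which may come from an annotation step that they share. Since 24 and 48 h differed while both have this mark, such a step is argued against as the whole cause of the difference in share. The exact permutation p was 0.00216 (n = 6 each, the smallest possible), with the libraries taken as independent though male and female of a number were paired. Means by number were 57.5% to 58.7% against 30.1% to 43.8%, a difference of 22.6 ± 4.24 (SE, n = 3 each, exact permutation p 0.1, the smallest possible). Gestational age, and rounds of library making that the labels do not give, may each account for it and were not separated.

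The 3' CCA change turned between times: the log2 ratio of 3' CCA fragments to miRNAs changed by 0.395 at 3 h and -0.170 at 24 h, a difference of 0.564 (n = 6 per arm, exact permutation p 6.79e-05), and for 3' fragments without CCA the difference was 0.261 (exact permutation p 0.021). Without CCA it was 0.418 in males and 0.104 in females (n = 3 per arm, exact permutation p 0.02 and 0.465). Their 24 h changes were -0.234 and 0.0432, so the females showed no fall there. These times were picked because the shares had passed in opposite directions in the same libraries, so these p add no evidence to those of the shares. The response differed between times for 25 small RNAs, but for 2 with library totals alone, and 0 of the 11 named and called in that test kept passing under every scaling. Among tRNA fragments the edgeR adjusted p of the treatment by time test was 0.00203 for SeC TCA misc, 0.00337 for Asp GTC leader, Glu TTC misc, Asp GTC tRF1 and Thr CGT tRF1, and 0.00561 for Asp GTC misc. It was 0.0104 for Ala TGC tRF3CCA and Ala CGC tRF3CCA, 0.0222 for Ser GCT tRF1, 0.0259 for Thr AGT tRF1, 0.0317 for Leu AAG tRF3CCA, 0.0339 for Ser AGA tRF1, 0.0351 for Ala AGC tRF3CCA, 0.0354 for Cys GCA tRF3CCA, 0.0384 for Leu TAG tRF3CCA and 0.039 for Val TAC tRF1. Among miRNAs it was 0.0339 for miR-124-1-3p and miR-29b-3p and 0.0374 for miR-376a-3p. The response of miR-28c-3p differed between the sexes at 12 h by -4.07 (n = 2 each), which did not pass with the replicate block or without saline male 1 (edgeR adjusted p 0.101 and 0.0621).

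Single libraries far from the rest of their group were searched in 470 groups of 4 to 10 libraries, and 31 had one (6.6%), where chance gives about 5%. Fetal brain male 3 had a total of 123.7 in units of 1e6 counts, the others 6.705 to 48.9. At 48 h poly(I:C) female 2 held 0.1673% of its counts in tRF3 (others 0.09832 to 0.113) and 0.4367% in tRF3CCA (0.2271 to 0.2543). At 12 h saline female 2 held 0.5224% in tRF1 (0.4153 to 0.4328) and poly(I:C) male 2 held 0.3098% in tRF3CCA (0.2361 to 0.2432), and at 24 h saline male 1 held 0.3091% in tRF1 (0.2632 to 0.2771).

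In CPM of the library total, without TMM, 3 h saline female 1 (53.6% tRNA fragments, the highest of its arm) stood apart in 6 small RNAs: miR-155-5p at 288.2 (others 371.6 to 406.6), miR-146a-5p at 732.6 (910.3 to 951.5), Ala AGC tRF3CCA at 175.5, Ser AGA tRF1 at 28.08, Cys GCA tRF3CCA at 76.14 and Cys GCA misc at 173. Lys CTT tiR5 stood at 33440 in 3 h saline female 2, and miR-6240-3p at 2774 in 6 h poly(I:C) male 1 (others 1178 to 1731). miR-466a-3p stood at 14.77 in 12 h saline female 2. At 24 h under poly(I:C) miR-155-5p stood at 366.9 in male 2 (others 195.6 to 217.6), miR-21a-5p at 5095 in female 3 (7624 to 8812; 67.9% tRNA fragments, the highest of its arm) and Arg ACG tRF5 at 7.764 in female 2 (1.432 to 3.689). At 24 h under saline male 3 held miR-488-3p at 0 and miR-196b-5p at 1874, and fetal liver male 3 held miR-291b-5p at 2.29 and miR-124-1-3p at 1.564. miR-122-5p stood at 613.2 in 3 h poly(I:C) male 2 (others 69.78 to 118.3), without which 3 h gave 54 calls (47 of the 56), and at 121.9 in 6 h saline male 3 (62.03 to 83.84). miR-451a stood at 89.22 in 24 h poly(I:C) male 2 (24.3 to 48.58). miR-9-5p stood at 60.75 in 3 h saline male 1 (14.19 to 22.5) and 26.85 in 144 h saline female 4 (9.725 to 15.47), and miR-124-3p at 4.026 in 3 h poly(I:C) male 1 and 3.907 in 6 h poly(I:C) male 2. miR-21-5p stood at 43130 in 48 h saline female 2, and miR-141-3p at 547.7 in 144 h saline male 1.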

How the results depend on the processing

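The settings with part of the times, with the tiR5 share as a covariate, with 3 h as the reference of the fetal tissues and with thinned libraries were added after the data were seen; the rest were planned. The cause of a moved count was not tested, except that fewer times leave fewer libraries. The tissue and age counts stayed within 1.5 times of their values under another scaling, test or block. The tRNA fragment share kept its side of the threshold without the most abundant small RNA of each class (averaging male and female leaves 3 against 3 at most times, which cannot pass), and its direction at each time but 48 h (-0.0480, and 0.520 without the most abundant). Of 2076 values of single small RNAs under another setting, 1837 kept their direction and side of the threshold, 194 no longer passed, 44 newly passed and 1 turned.

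With DESeq2 as the test, 3 h gave 99 calls (65 higher, 34 lower, 56 shared), 6 h 22, 24 h 24 (12 and 12), 144 h 1, treatment by time 39, and male against female 11 in placenta/decidua (2 and 9), 12 in brain (8 and 4) and 9 in liver (8 and 1). DESeq2 size factors gave 144 h 1, placenta/decidua sex 4 and liver sex 0. With library totals alone, 3 h gave 126 (118 and 8, 47 shared), 48 h 0, treatment by time 2 and placenta/decidua sex 0, and Gly GCC tiR5 turned between brain and liver (-0.0266). miRNAs and tRNA fragments scaled separately gave 6 h 7 (6 and 1), treatment by sex at 12 h 2, treatment by time 14 and liver sex 3. The 3' fragment list turned there in placenta/decidua sex (camera adjusted p 0.937) and in brain against liver (0.676). Without the filter, 24 h gave 12, 48 h 9, 144 h 1, treatment by sex 1 at 3 h, 3 at 12 h and 2 at 48 h, treatment by time 10, and sex 1 in placenta/decidua, 5 in brain and 2 in liver. All 72 libraries in one fit gave 3 h 16 (14 and 2, 15 shared), 24 h 22 (19 and 3, 2 shared), 48 h 28 (26 and 2) and 144 h 1. Counts summed over the male and female of a number gave 24 h 1 and 48 h 0. limma-voom with the number as a random block gave 24 h 3 and 48 h 0. Of the single small RNAs named for poly(I:C), 21 no longer passed with summed counts and 73 were unchanged. With limma-voom 16 no longer passed and 78 were unchanged. As 24 and 48 h had only 5 and 1 named calls, most of these losses lie at 3 and 6 h.

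With the replicate block, 67 small RNAs differed between the sexes in brain and 62 in liver, where the numbers pair the libraries. The numbers did not pair control with poly(I:C) in both sexes of any time with 3 or more numbers (12 h has 2, too few to judge): 21 of 36 pairs correlated above 0.1 and 18 of 36 libraries correlated best with their own number. There the block gave 17 at 24 h (11 and 6). Placenta/decidua of male and female shared only a number in part of the arms, and the block gave 10 for sex in saline and 0 for treatment by sex at 12 h. It changed no other call of a comparison.

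The tiR5 share as a covariate gave 24 h 2 and 48 h 2. The 3, 6 and 144 h libraries alone gave treatment by time 15 and sex 0, and the 12, 24 and 48 h libraries alone gave treatment by time 0, sex 0 and 267 for any difference between times. Lists called under treatment, sex, tissue and age (22, 11, 43 and 9 as reported) came to 0, 1, 13 and 4 with an estimated correlation, to 2, 3, 67 and 20 with fry, and sex lists to 7 with separate scaling.

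With each library left out in turn, the counts ranged from 38 to 81 at 3 h (37 or more shared), 7 to 19 at 6 h, 0 to 1 at 12 h, 3 to 6 at 24 h, 0 to 2 at 48 h and 0 to 2 at 144 h. Treatment by sex ranged from 0 to 2 at 3 h, 0 to 3 at 12 h and 0 to 5 at 48 h, and stayed at 0 at 6, 24 and 144 h. Treatment by time ranged from 14 to 31, sex from 0 to 9 in placenta/decidua, 1 to 3 in brain and 0 to 3 in liver. Brain against placenta/decidua ranged from 1064 to 1116, liver from 977 to 1020, brain against liver from 962 to 1003, 144 h against 3 h from 713 to 757 and any time from 974 to 1005. The difference of the tRNA fragment share ranged from -8.80 to -6.31 percentage points at 3 h. Leaving out 1 library of 12 h leaves 1 in that sex and arm, which is assumed to vary like the others. What depth limits was not separated from spread: of small RNAs changed 1.5-fold in simulated libraries, 24% were recovered at 48 h, where the placenta/decidua totals were lowest, but 3% in the deeper fetal brain and 0% in fetal liver (3 against 3 libraries).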

Other observations

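The tests in this part were set before their results were seen, except the counts of other splits for the poly(I:C) comparisons and the genes singled out in the fetal tissues, which were chosen after.

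With the block, single members of the epithelial and let-7 lists, which camera had called in brain without it, passed. The miR-200 family of epithelia was higher in male brain, with miR-200b-3p, miR-200a-3p, miR-429-3p and miR-200c-3p (0.74) past the threshold, while miR-205-5p (-2.27) and miR-203-3p (-0.577) of the same list were lower, and let-7b-5p rose by 0.44. In male liver the higher miRNAs also held miR-133a-2-3p (0.99) of striated muscle and miR-142a-5p (0.76) of leukocytes.

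X-linked miRNAs were lower in male saline placenta/decidua, with miR-743a-3p, miR-503-5p and miR-741-3p among the smallest p. The 36 poly(I:C) libraries, which did not enter that comparison, were used to test whether the difference is seen again. There 59 of 78 X-linked miRNAs were lower in the male with a median of -0.0596, with a fry p of 0.0551 and a camera p of 0.00195 (0.14 with an estimated correlation). A p just above the threshold shows neither presence nor absence, so the hypothesis stays open. Across genes, which are not independent replicates, the male against female changes under saline and poly(I:C) had a Spearman rho of 0.318 over 76 X-linked miRNAs and 0.105 over 1297 small RNAs.

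The turn of the 3' CCA fragments, higher at 3 h and lower at 24 h, was split by sex. The treatment change at 3 h minus that at 24 h was 0.729 in males and 0.399 in females (log2, n = 3 per arm, exact permutation p 0.01 and 0.025). Both sexes had it in one direction, but the times were picked because these libraries together had passed in opposite directions, so this is no independent test and the question stays open.

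Other splits of the same libraries showed where chance can be excluded. For 6 h (1 of 100, 14 real, highest other 13) it can be only if the libraries are taken as independent. The labels do not say what a number means, and the real count there lay little above the highest other. The same condition holds for 3 h (1 of 100, 56 real, highest other 5). Male and female of a number were paired in the poly(I:C) arm there. The condition also applies to placenta/decidua sex (1 of 100, 2 real, highest other 1), where the real split parts the pairs of 24 and 48 h. Of those 2 calls, 0 kept passing with every library left out. With the libraries taken as independent, chance can also be excluded for the tissue and age comparisons, each with 1 of 100: brain against placenta/decidua (1084 real, highest other 403), liver against placenta/decidua (1008, 612), brain against liver (978, 483), 144 h against 3 h (737, 564) and any time (991, 249). For 24 h with 2 of 100 (5 real, 8), 48 h with 4 of 100 (1 real, 19) and treatment by time with 2 of 100 (25 real, 33) it can be only if the libraries are taken as independent, though male and female of a number were paired at 24 and 48 h. Summed over a number the calls of these times were 1 and 0, and with limma-voom 3 and 0. Where the real count was 0 every split gives as many, so the splits say nothing: 34 of 34 at 12 h (highest other 32), 100 of 100 at 144 h (44), and 100 of 100 for treatment by sex at 3, 6, 24, 48 and 144 h (highest others 8, 50, 1, 95 and 4). For treatment by sex at 12 h (4 of 18 splits, 1 real, 55), brain sex (1 of 10, 2 real, 0) and liver sex (1 of 10, 1 real, 0) the splits are too few. In brain and liver 4 of the 10 splits part all 3 pairs of numbers, and the 3 others among them gave 0.

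Splits with many more calls than the real one, 32 at 12 h, 19 at 48 h, 44 at 144 h and up to 95 in treatment by sex, point to a structure of the libraries other than treatment and sex. For the counts of lists, chance cannot be excluded for treatment (10 of 34 splits gave as many as the 22, highest other 43), placenta/decidua sex (39 of 100, 5 real, 12), tissues (9 of 100, 43 real, 45) and 144 h against 3 h (32 of 100, 9 real, 14). For the lists in brain sex (8 of 10 splits, 2 real, 6) and liver sex (5 of 10, 4 real, 7) the splits are too few.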
